A study of Sus scrofa with 4 samples.

How the data were processed

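The series compared porcine blastocysts exposed to ethanol from the zygote stage with unexposed blastocysts. RNA was extracted from pools of 10 embryos, amplified in 2 rounds of T7 transcription and labelled by a platinum-linked chemistry that attaches Cy3 or Cy5 to guanine, per the labels' protocols. Each of the 4 arrays held 1 ethanol pool and 1 control pool, with the dyes swapped between arrays 1 and 3 and arrays 2 and 4, per the labels. The series description gives 4 pools of each kind, and these were treated as 4 independent replicate pairs. Whether the pools came from separate cultures or oocyte collections was not given in the sources used here, so their independence is unknown. Slide and scan date were not given in the sources used here, so no batch was tested.

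The deposited scanner values were spot and local background intensity for both dyes, not normalized, per the file headers. Scanner, software and version were not given in the sources used here. Median pixel intensities were used, a choice made before any test because the authors' values matched them closely. The authors' deposited series table holds log2 ratios. Set against loess-normalized log2 Cy5 over Cy3 ratios of background-subtracted medians, its columns correlated across probes at 0.989, 0.997, 0.995 and 0.986 for arrays 1 to 4, with slopes of 0.977, 0.993, 0.930 and 1.02. Its scale is therefore log2, its direction Cy5 over Cy3 on every array, and its column medians were -0.0138, -9.35e-05, 0.00378 and 0.00108. The authors' normalization method was not given in the sources used here. A further table with 4 per-array columns whose names match no single label was not used.

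Analysis was done in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and ratios were normalized within each array by loess, with weight 0 for the 1426 control and other non-probe spots, which were then left out. A probe counted as above background in a channel when its signal exceeded the 95th percentile of the 153 negative-control spots of that array and channel. It was kept when this held on at least 3 arrays for ethanol RNA or on at least 3 for control RNA, which left 25899 of 43794 probes. At most 2 spots of an array were saturated, and none was removed. The model had a coefficient for ethanol over control, with the sign set by the dye orientation, and a dye coefficient for each probe, which left 2 residual degrees of freedom. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all kept probes, and the threshold was 0.05.

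Gene names are those of the array's annotation. It gives 1 symbol for 18121 probes, several for 0 and none for 25673, and the unnamed probes were tested but not named here. Placeholder symbols (1024 probes) were set aside. Of 4740 probes with an accession, 2658 matched a transcript of the Sscrofa11.1 RefSeq table, which was used for names only, and 124 of these carry another symbol there. The array's names were kept. A gene stands on its brightest kept probe. Of 2055 genes with over 1 kept probe, 968 had probes that differed in direction.

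The comparison, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and the 10 largest falls past the adjusted threshold with the same sign on all 4 arrays. Where fewer pass, it fills each direction to 10 with the genes of smallest p that keep one sign. It adds up to 4 members of smallest p from each list, and ADH5, ALDH2, ALDH1A1 and CAT where measured. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over 27 lists. The alternatives covered background correction, normalization, the filter on dim probes, the dye term, the variance model, separate-channel analysis, the authors' values, leaving out each array, averaging a gene's probes, camera with an estimated correlation, and fry. Mean in place of median pixel signals was added after seeing the data. Intervals of fold changes are 95% intervals of the moderated fit.

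The procedure was tested on simulated data for the ethanol over control comparison. Noise variances were drawn from the fitted prior and each of 25899 probes kept its measured dye coefficient, with 200 probes changed by known folds. The adjusted threshold found 18 of 50 probes changed 1.5-fold, 44 of 50 changed 2-fold, 50 of 50 changed 3-fold and 50 of 50 changed 4-fold, and called 12 unchanged probes. In the list step, over 7343 genes and 50 simulated data sets, camera called 1 of 1350 list tests without an effect. A ribosomal list lowered by 0.2 was called in 50 of 50. The simulation draws noise independently between genes. Its shares found hold for data with 200 such changes. The Benjamini-Hochberg cut-off is stricter when fewer probes change, and that case was not simulated.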

Results

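Transcript levels were measured in porcine expanded blastocysts that had developed from the zygote for 7 days with or without 0.2% ethanol. The embryos were kept in PZM3, a culture medium for pig embryos. The comparison addresses which transcripts differ in embryos that reach the blastocyst stage despite ethanol. Each of 4 two-colour arrays carried amplified RNA from 1 pool of 10 ethanol-exposed blastocysts and 1 pool of 10 control blastocysts. Ethanol RNA was labelled with Cy5 on arrays 1 and 3 and with Cy3 on arrays 2 and 4. Of 43794 probes, 25899 (59.1%) were kept as above background, and 10842 of these carried a usable gene symbol for 7343 genes. The Cy3 channel showed 70.4% to 73.5% of probes above background and the Cy5 channel 45.3% to 57.3%. Values below are log2 ratios of ethanol over control from the limma fit with the dye term, with its standard error (SE). The fit covers the 4 arrays, whose number limits the precision. Ratios of single arrays before the dye term can follow the dye and differ in sign from the fitted value. The pools are the replicates, and their independence is not stated. Each SE and each gene's p-value rests on the spread between these 4 pairs of pools, which limma moderates with that of the other probes.

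Ethanol-exposed and control blastocysts were compared gene by gene. No gene passed the adjustment for multiple testing, so the 10 genes of smallest p in each direction are given as values. They were taken from genes with one sign on all 4 arrays and encode proteins of varied function. Among the 10 in the higher direction, CLU, which encodes the secreted chaperone clusterin, had a log2 ratio of 0.97 (SE 0.14, 1.96-fold). ALOX5, the 5-lipoxygenase of leukotriene synthesis, had 0.76 (SE 0.12). ATP6V0D2, a subunit of the vacuolar proton pump, had 0.72 (SE 0.10). TIMP2, an inhibitor of matrix metalloproteinases, had 0.71 (SE 0.07, 1.63-fold), and the aldehyde dehydrogenase gene ALDH9A1 had 0.71 (SE 0.08, 1.63-fold). HTRA1, a secreted serine protease, had 0.61 (SE 0.07), and its probe was above background in the control channel of 2 of the 4 arrays. The signalling adaptor GRB2 (0.58), the kinase scaffold AKAP12 (0.49), the ER retrieval receptor KDELR3 (0.45) and RASSF8 (0.43) completed the 10.

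In the lower direction, MIOX, which encodes the oxygenase that opens the inositol ring, had a log2 ratio of -0.86 (SE 0.10, n = 4), a 1.82-fold difference, and all 6 of its kept probes lay between -0.86 and -0.50. TRPT1, a tRNA phosphotransferase, had -0.74 (SE 0.10), while a second TRPT1 probe lay at 0.01. STXBP2, which acts in vesicle fusion, had -0.60 (SE 0.09), and AGPAT1, an acyltransferase of phospholipid synthesis, had -0.59 (SE 0.09). ALKBH7, a mitochondrial dioxygenase, had -0.52 on its brightest probe and -0.46 on the other. The remaining genes were FCER1G (-0.50), MIPEP (-0.49), TBL3 (-0.47), RAP2A (-0.44) and NGEF (-0.43). Of the 7 probes of MIPEP, a mitochondrial peptidase, 6 lay below 0 and 1 at 0.02. The pair of AKAP12 probes lay at 0.49 and 0.00, so the values of TRPT1, MIPEP and AKAP12 shrank by over 1.5 times when probes of a gene were averaged.

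**Figure D1:**
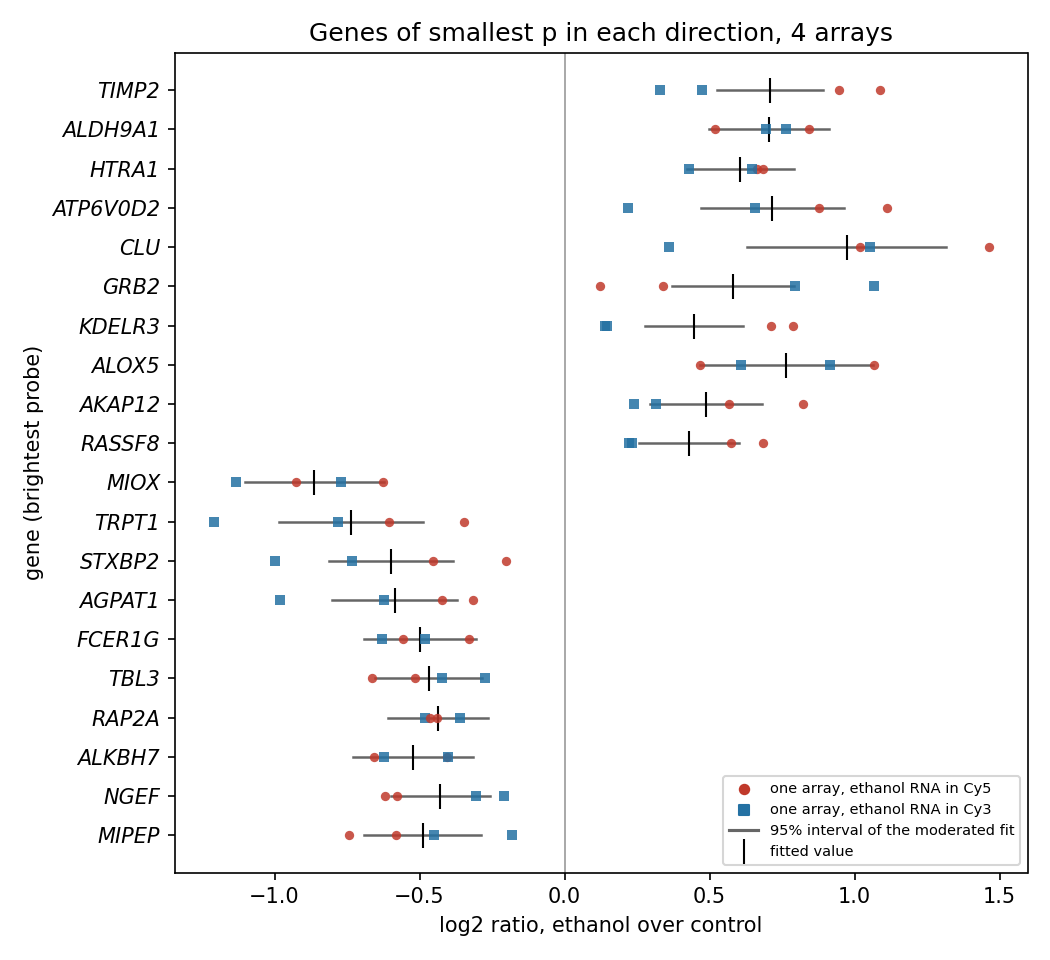
Log2 ratio of ethanol over control (x axis) for the 10 genes of smallest p in each direction (y axis), with 1 point per array coloured by the dye of the ethanol RNA, a tick for the fitted value and a line for its 95% interval. Of these 20 genes, CLU lies highest at 0.97 and MIOX lowest at -0.86, and none passed the adjusted threshold.

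Across all probes, limma called 0 of 25899 at an adjusted p under 0.05, and the smallest adjusted p was 0.511. At an unadjusted p under 0.05 there were 1883 probes, against 1295 expected by chance. Taken on their brightest probe, 663 of the 7343 genes were under this p, 355 higher and 308 lower, against 367 expected. The count past the adjusted threshold was also 0 without the dye term, with separate channels and with the authors' processed values, which gave 879, 2609 and 1872 probes at an unadjusted p under 0.05. An unadjusted p under 0.05 together with a 1.5-fold difference and the same sign on all arrays was met by 47 probes and by 18 named genes, 11 higher and 7 lower. That gene count was 64 without array 4, 41 without array 3, 53 with a normexp offset of 0 and 10 with mean in place of median pixel signals, a setting chosen after seeing the data.

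Genes encoding ribosomal proteins of the cytosolic ribosome were lower with ethanol as a group. Their median log2 ratio was -0.19 over 45 measured genes, of which 42 lay below 0, and this was the only 1 of 27 tested lists past the adjusted threshold of limma's camera (adjusted p = 3.01e-17). At the preset correlation, camera sets a list's genes against all other genes, so this p-value does not measure the spread between pools. With an estimated correlation the list did not pass (adjusted p = 0.428), nor did it in fry's test for one direction (adjusted p = 0.095), while it passed fry's test for change in either direction (adjusted p = 0.00797). RPL13A had a log2 ratio of -0.46 (SE 0.09), RPS28 -0.43 (SE 0.07), RPS3A -0.38 (SE 0.07) and RPS24 -0.37 (SE 0.07). With a gene's probes averaged, RPL13A had -0.29 and RPS3A -0.19. No member passed over all probes, and 10 passed when adjusted over the list alone. The ratio before the dye term followed the dye: the list's median was 0.16 and 0.23 on the arrays with ethanol RNA in Cy5 and -0.62 and -0.59 on those with ethanol RNA in Cy3. The members' median dye coefficient, the part of the log ratio that stayed with Cy5, was 0.44, larger than the difference between treatments.

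**Figure D2:**
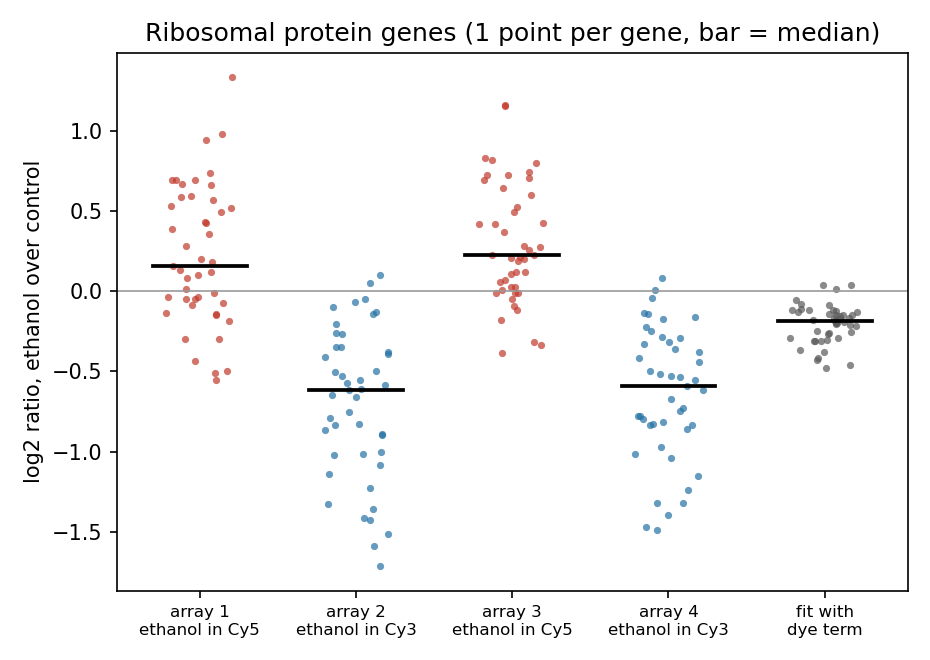
Log2 ratio of ethanol over control (y axis) of 45 ribosomal protein genes, 1 point per gene and a bar at the median, on each array and in the fit with the dye term (x axis). The medians are 0.16 and 0.23 with ethanol RNA in Cy5, -0.62 and -0.59 with ethanol RNA in Cy3, and -0.19 in the fit.

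Genes of ethanol and aldehyde metabolism gave a single large value. Of the 17 measured, 4 lay above 0 and 13 below, with a median of -0.02. ALDH9A1, which oxidises aminoaldehydes, was 1 of 17 measured members and the only member that passed when adjusted over the list alone (adjusted p = 0.00316 by limma), and it did not pass over all probes. ALDH6A1 had a log2 ratio of -0.31 (SE 0.08), ACSS2, which makes acetyl-CoA from acetate, 0.37 (SE 0.17; 0.13 without array 1), and ADH5, the class III alcohol dehydrogenase, -0.02 (SE 0.09). CAT, the catalase gene, had 0.04 (SE 0.09). ALDH2 and ALDH1A1 had no kept probe under those names. The list did not pass camera (adjusted p = 0.685), while fry's test for change in either direction gave an adjusted p of 0.0118. Of 30 antioxidant and glutathione genes, 17 lay above 0 and 13 below, and none passed over all probes or over the list alone. SOD1 (0.25, SE 0.08), MGST3 (0.29, SE 0.10) and TALDO1 (-0.31, SE 0.09) had among the smallest p. Before the dye term TALDO1 had 0.24 and 0.60 with ethanol RNA in Cy5 and -1.10 and -0.97 with it in Cy3.

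Lipid genes went both ways. Among 31 genes of fatty acid oxidation, synthesis and storage, none passed over all probes and 2 passed when adjusted over the list alone. These were the acyl-CoA dehydrogenases ACADL, at 0.67 (SE 0.12), and ACADVL, at -0.57 (SE 0.11), which act on long and very long chains. ACAA2, the mitochondrial thiolase, had 0.30 (SE 0.08), and LIPE, the hormone-sensitive lipase, -0.34 (SE 0.09). The list did not pass camera (adjusted p = 0.346) and had an adjusted p of 0.00343 in fry's test for change in either direction. The 13 measured genes of cholesterol synthesis and uptake had a median of 0.12, with 9 above 0 and none passing, and CYP51A1, the lanosterol demethylase, had 0.39 (SE 0.16) and ACAT2 0.28 (SE 0.12). Without array 1 these values were 0.18 and 0.11. A probe listed under the pig's symbol CYP51 was brighter than the CYP51A1 probe (mean log2 intensity 13.0 against 9.3) and had 0.68 (SE 0.20). The list held only the name CYP51A1, so its value for this gene rests on the dimmer probe. The list of cholesterol synthesis and uptake did not pass camera (adjusted p = 0.218), and its median depended on single arrays. It was 0.01 without array 1 (adjusted p = 0.946) and 0.03 without array 4 (adjusted p = 0.851), against 0.20 without array 2 (adjusted p = 0.0249) and 0.23 without array 3 (adjusted p = 0.00121). This list also passed camera in a split of the arrays that did not contrast ethanol with control (adjusted p = 0.00178).

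**Figure D3:**
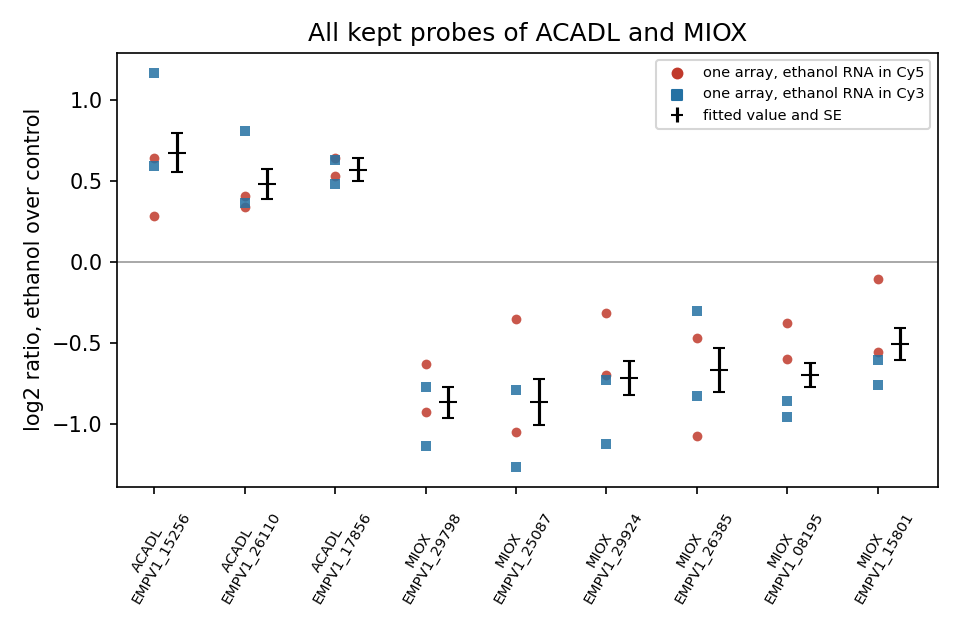
Log2 ratio of ethanol over control (y axis) for every kept probe of ACADL and MIOX (x axis), with 1 point per array coloured by the dye of the ethanol RNA and the fitted value with its SE. The 3 ACADL probes have fitted values from 0.48 to 0.67 and the 6 MIOX probes from -0.86 to -0.50.

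In energy metabolism, the 17 genes of glycolysis and lactate included 13 above 0. Those of smallest p were LDHA, lactate dehydrogenase A, at 0.37 (SE 0.08), and TPI1, triosephosphate isomerase, at 0.30 (SE 0.07), and the pyruvate dehydrogenase kinase gene PDK3 had 0.34, or 0.10 without array 1. The 46 nuclear-encoded genes of oxidative phosphorylation had a median of -0.04, with 32 below 0, and the complex I subunits NDUFB7 and NDUFA7 had -0.35 (SE 0.09) and -0.26 (SE 0.07). Neither list passed camera (adjusted p = 0.218 and adjusted p = 0.203), and both depended on single arrays. Without array 3 both passed (adjusted p = 0.0457 and adjusted p = 0.00887). Without array 1 the median of glycolysis and lactate was -0.02 and that of nuclear-encoded oxidative phosphorylation -0.02 (adjusted p = 0.760 for both), and without array 2 the latter was also -0.02 (adjusted p = 0.547), against -0.09 without array 3 and -0.08 without array 4 (adjusted p = 0.0739). The glycolysis median was 0.04 with all arrays, 0.07 without array 2, 0.13 without array 3 and 0.01 without array 4. The oxidative phosphorylation list passed with mean pixel signals (adjusted p = 0.0274). It also passed camera in a split of the arrays that did not contrast ethanol with control (adjusted p = 0.009998). Among 19 hypoxia-response genes the median was 0.06, 13 lay above 0, and ADM, which encodes adrenomedullin, had 0.29 (SE 0.07). That hypoxia response list did not pass either (adjusted p = 0.203), and its median was 0.07 to 0.10 with 1 array left out and 0.09 with a normexp offset of 0. With mean pixel signals and with the authors' values the hypoxia median was 0.04. The 28 genes of mitochondrial biogenesis, dynamics and translation were split into 14 above and 14 below 0, with the fusion GTPase OPA1 at 0.30 (SE 0.09), or 0.16 with its probes averaged. No member of these 4 lists passed over all probes or over its list alone. The list of mitochondrially encoded genes had 1 measured member and was not tested.

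Among 29 genes of apoptosis and the p53 response, none passed over all probes and BAX, a pro-apoptotic pore former, passed over the list alone with a log2 ratio of -0.42 (SE 0.07). The anti-apoptotic BCL2L1 had -0.50 (SE 0.13), the pro-apoptotic BCL2L11 -0.28 (SE 0.09) and MDM2, a target and inhibitor of p53, 0.28 (SE 0.10). With 1 array left out the values nearest to 0 were -0.33, -0.18 and 0.15. Of 37 genes of the unfolded protein and heat shock responses, 21 lay above 0. The protein disulphide isomerases PDIA4 and PDIA3 had 0.33 (SE 0.09) and 0.28 (SE 0.08), and the ER chaperone CALR had -0.29 (SE 0.09), or -0.20 without array 1. The 25 autophagy and lysosome genes included the cathepsin gene that the array calls CTSL1, at 0.35 (SE 0.08), and GAA, lysosomal alpha-glucosidase, at -0.29 (SE 0.07). In 25 genes of interferon and inflammatory responses, the chemokine gene IL8 (CXCL8), above background in the ethanol channel of 3 arrays, had -0.47 (SE 0.10, or -0.81 with a normexp offset of 0). STAT2 had -0.26 (SE 0.09). Before the dye term STAT2 had 0.23 and 0.49 with ethanol RNA in Cy5 and -1.02 and -0.75 with it in Cy3. None of these 4 lists passed camera, with adjusted p of 0.904, 0.345, 0.753 and 0.746.

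Genes of DNA methylation and one-carbon metabolism gave 2 members that passed over the list alone and none over all probes, of 17 measured. TET1, which oxidises methylcytosine, had a log2 ratio of 0.56 (SE 0.12), and DNMT1, the maintenance methyltransferase, had 0.35 (SE 0.07) with its 3 probes between 0.25 and 0.35. SHMT2 had 0.25 (SE 0.08), or 0.14 with its probes averaged. The list's adjusted p in camera was 0.218. None of 13 imprinted genes passed over all probes or over the list alone, with MEST at -0.22 (SE 0.12), or -0.07 without array 2. In 14 genes of retinoic acid metabolism and response, CYP26A1, which degrades retinoic acid, had 0.32 (SE 0.15), above background in the ethanol channel of 3 arrays, and 0.13 without array 3. The adjusted p of these lists was 0.773 and 0.501.

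Markers of the blastocyst's cell lineages did not pass as lists or as single genes. The 23 trophectoderm genes had a median of -0.07, with 14 below 0 and values from -0.62 to 0.29 (adjusted p = 0.218 by camera). The trophectoderm median was -0.05 without array 4 and -0.04 without the filter on dim probes. The placental aspartic protease gene PPAG3 had -0.38 (SE 0.07), TEAD4 -0.29 (SE 0.09) and GATA2 -0.18 (SE 0.07). Of 12 inner cell mass and pluripotency genes, 9 lay below 0, with DPPA5 at -0.27 (SE 0.11) and ESRRB at -0.26 (SE 0.10), above background in the ethanol channel of 3 arrays (adjusted p = 0.321 for the list). The 13 hypoblast genes included 8 above 0, with the basement membrane genes COL4A1 at 0.27 (SE 0.12) and LAMC1 at 0.23 (SE 0.11) (adjusted p = 0.398). Of the 22 genes of cavity formation, 13 lay above 0 and 9 below, with values from -0.62 to 0.34 (adjusted p = 0.346). Those of smallest p were the polarity kinase PRKCI, at 0.34 (SE 0.09), and the desmosomal DSP, at 0.30 (SE 0.10). The control channel of PRKCI was above background on 3 arrays. Among 19 maternal oocyte transcripts, KPNA7 had -0.39 (SE 0.13) and ZP4 0.22 (SE 0.09) (adjusted p = 0.440). With 1 array left out the values nearest to 0 were -0.18 for TEAD4, -0.13 for DPPA5, -0.14 for ESRRB, 0.15 for COL4A1, 0.11 for LAMC1 and -0.22 for KPNA7.

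Markers of cells that could accompany the embryos were also compared. Of 18 cumulus and granulosa genes, none passed over all probes and 2 passed over the list alone, RGS2 at 0.53 (SE 0.08) and VNN1 at -0.40 (SE 0.09), which went opposite ways (adjusted p = 0.746 for the list). With its probes averaged RGS2 had 0.23. Before the dye term RGS2 had -0.12 and 0.15 with ethanol RNA in Cy5 and 1.03 and 1.06 with it in Cy3. VNN1 had -0.97 and -0.82 with ethanol RNA in Cy5 and -0.10 and 0.30 with it in Cy3. The 6 measured sperm and blood cell genes lay between -0.06 and 0.16 (adjusted p = 0.685). Signalling and growth genes were compared as 4 further lists. The largest fitted values among those of smallest p were TGFB3 at 0.28 (SE 0.08) in 30 genes of TGF-beta, BMP and FGF signalling, CTNNB1, beta-catenin, at 0.20 (SE 0.09) in 20 Wnt genes, MCM4 at 0.28 (SE 0.12) in 29 cell cycle genes, and the creatine transporter SLC6A8 at -0.42 (SE 0.16) in 16 transporter genes. The adjusted p of these 4 lists was 0.218, 0.746, 0.499 and 0.484, and no member passed over all probes or over its list alone. The second MCM4 probe went the other way, and with both averaged MCM4 had 0.06. With 1 array left out the values nearest to 0 were 0.13 for MCM4, -0.21 for SLC6A8 and 0.11 for CTNNB1.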

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

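The search for an array far from the other 3 covered 166 values and was set before the data were examined. Ratios before the dye term were searched, where a dye bias sets arrays 1 and 3 apart from arrays 2 and 4. The usual chance rate of about 1 in 20 therefore need not hold. The search marked 4 genes. TNNI3, cardiac troponin I, stood at -2.54 on array 3 and between -0.44 and -0.36 on the others. TNNI3 entered the set of 18 genes at 1.5-fold with a fitted value of -0.94 (SE 0.33), and without array 3 its value was -0.40. TEAD4 stood at 0.060 on array 4 and between -0.42 and -0.37 on the others, and CTNNB1 at 0.48 on array 2 and between 0.07 and 0.12 on the others. HTRA1 stood at 0.43 on array 2 and between 0.65 and 0.68 on the others. No explanation was tested for these 4 genes.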

How the results depend on the processing

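Mean pixel signals were chosen after seeing the data; the other alternatives were not. The number of genes past the adjusted threshold was 0 under all 16 alternatives, and the smallest adjusted p reached 0.0542 without array 3. The 18 genes at 1.5-fold became 53 with a normexp offset of 0 and 10 with mean pixel signals, and 18 to 64 when 1 array was left out. Of the 18, 12 to 14 stood in the sets without an array, and 18 in the set with offset 0; that offset and a lost array both widen the ratios or loosen the sign rule by construction. The count of lists past the threshold, 1, became 2 with mean pixel signals, 0 with camera's estimated correlation, 0 with fry for one direction, 3 with fry for mixed directions, and 1 to 4 when 1 array was left out; the cause was not tested. The ribosomal median of -0.19 kept its sign and call in every refit and lost its call only with the estimated correlation (adjusted p = 0.428), which rests on the 2 residual degrees of freedom, and with fry for one direction (adjusted p = 0.095). Aquantile leaves within-array ratios as they are and so tested nothing here. In this balanced design the log2 ratios also stay the same without the dye term, with the other variance model and with separate channels. None of 447 values of the 28 genes leading by p or in the 1.5-fold set changed sign. These genes were chosen for one sign on all 4 arrays, so leaving out 1 array could not turn them. The lack of reversals was thus largely fixed in advance. With offset 0, HTRA1 had 1.13, KDELR3 0.67 and RAP2A -0.66, and with mean pixel signals KDELR3 had 0.24. Of all 134 named genes, 83 had a value over 1.5 times larger or smaller, or of the other sign, under at least 1 alternative. Offset 0 gave IL8 -0.81, CYP26A1 0.56, PRKCI 0.55, ESRRB -0.47 and DSP 0.46, and mean pixel signals gave KPNA7 -0.23, LIPE -0.22, PDK3 0.21, DSP 0.19, ZP4 0.14 and ESRRB -0.11. Signs turned for 5 other genes near 0, for which the cause was not tested. ALDH16A1 had 0.033 without the filter and 0.10 with mean pixel signals, ADH5 had 0.021 with averaged probes and -0.12 to 0.080 when 1 array was left out, and CAT had -0.000665 with the authors' values and -0.067 to 0.14 when 1 array was left out. RARB ran from -0.053 to 0.30 and CD3E from -0.000639 to 0.11 in the same way. Low Cy5 signal limits dim probes: 16614 of the 25899 kept probes were above background in both channels of all 4 arrays.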

Other observations

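Several genes were read by 3 or more kept probes that all gave one direction. Of 798 genes with at least 3 kept probes, 9 had every probe at an unadjusted p under 0.05 on one side of 0, 2 higher and 7 lower with ethanol, and none passed the adjusted threshold. The higher ones were ACADL, with 3 probes from 0.48 to 0.67, and DNMT1, with 3 from 0.25 to 0.35. Beside MIOX, the lower ones included EEF1D, a subunit of translation elongation factor 1, with 7 probes from -0.37 to -0.23, PHYHD1, a dioxygenase, with 5 from -0.41 to -0.25, and a gene the array calls MFSD7, with 4 from -0.42 to -0.24. ETFB, which passes electrons from fatty acid oxidation to the respiratory chain, had 3 probes from -0.44 to -0.30, the mitochondrial sulfhydryl oxidase GFER 3 from -0.37 to -0.21, and the prolyl hydroxylase EGLN2 3 from -0.34 to -0.25. These genes were picked out after their values were seen. Probes of one gene read the same RNA, so their agreement does not add replicates.

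Outside the rule for named genes, and chosen after seeing their values, the set of 18 genes at 1.5-fold also held GPX6, a glutathione peroxidase, at 0.81 (SE 0.21), ITIH5 at 0.74 (SE 0.13), and PRNP, the prion protein gene, at 0.60 (SE 0.12). A probe listed as CYP51, the pig's symbol for CYP51A1, had 0.68 (SE 0.20), or 0.45 without array 4, and the CYP51A1 probe had 0.39, or 0.18 without array 1. GRTP1 had -0.64 (SE 0.15) and MAP1S -0.61 (SE 0.12).

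In what follows, these tests were chosen only after the result was seen: the splits of the arrays for the counts of genes and lists, the 1.5-fold set and the ribosomal median, the lists matched on intensity, the comparison of dyes for MIOX, and the part of its test by array that covers the other 5 probes. The 4 arrays allow 3 balanced splits with the dye term kept, the real one included, too few for a share under 0.05. At an unadjusted p under 0.05 with 1.5-fold and one sign, the real split gave 47 probes and the highest other split 19, and 1 split gave as many as the real one. Genes past the adjusted threshold numbered 0 in the real split and at most 0 in the others. With a real count of 0 all 3 splits had to give as many, so this comparison tested nothing. All 3 splits also gave as many lists, with 1 in the real split and 1 in the highest other. Genes whose 3 or more probes all went one way numbered 9 in the real split and 3 in the highest other, and 1 split gave as many.

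For the lower ribosomal protein genes, a bias of bright probes was argued against. Lists of other genes matched on intensity had medians from -0.06 to 0.02 (95% of 10000 lists). Their lowest median was -0.09, so the share at or below -0.19 is given as 1e-04, the smallest they can give. Genes were drawn independently and matched on intensity alone, not on dye coefficient. This share therefore does not measure the spread between pools or allow for genes that vary together. A dye bias that differed between arrays and was shared by bright genes in proportion to their dye coefficient was argued against too. A line through 262 other bright genes gave a log2 ratio of -0.019 at the ribosomal dye coefficient of 0.44 (95% interval -0.04 to 0.001). Their median dye coefficient was only 0.09, and the interval resamples genes as if they were independent. The fit cannot address a dye bias particular to ribosomal transcripts. A loss shared with the mitochondrial ribosome was not seen, as 52 genes of its proteins had a median of -0.0073 (95% interval -0.05 to 0.03). A hypothesis that ethanol lowered other messages of the same regulatory class, most of them of the translation machinery, stays open. The 18 such genes had a median of -0.083 (95% interval -0.20 to 0.05), with EEF1B2 at -0.44 and PABPC1 at 0.38. They included FAU (-0.21), which encodes a ribosomal protein but was not in the ribosomal list. Some were not translation machinery, such as VIM (0.43, SE 0.41). Splits cannot settle chance for the ribosomal list (median -0.19, highest other -0.05, 1 of 3 as large). Labelling or amplification effects specific to the short ribosomal protein transcripts may remain.

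For MIOX, which lay lower on all its probes, dye bias was argued against by the values per probe and array, 100% of which (24 of 24) lay below 0, although the 4 of the brightest probe did so by the rule that named the gene. No single array carried the value of the brightest probe, which leaving out an array moved by a factor of at most 1.12, to between -0.95 and -0.77. This is not an independent test, since a small p and one sign on all arrays had named that probe. The other 5 probes, which the rule did not use, lay between -1.04 and -0.39 with any array left out (20 of 20 values below 0 at an unadjusted p under 0.05). Their lower values had prompted the test, and they read the same RNA, so they are no independent check. The other splits gave at most 0.17 in size against -0.86, and 1 of 3 was as large, too few to judge chance. A lower level of MIOX RNA after ethanol may be followed up as a hypothesis, in a measurement with more pools, since it was found on these data and did not pass the adjusted threshold.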
